A study of Mus musculus with 8 samples.

How the data were processed

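Gene expression was measured on 8 Affymetrix mouse arrays, 4 from oligodendrocyte precursor cultures kept for 48 hr at 31.5 °C and 4 from cultures kept at 37 °C. The deposited table holds linear probe set intensity values, made by the authors with MAS5 per the labels, which give no version and no scaling target. No detection calls came with the values. The deposited intensity values were not at a common level: the 2% trimmed means differed between arrays by a factor of 1.889. No genome build or coordinates were used, and genes are given by symbol and probe set.

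Of the 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 carried 1 gene symbol, 932 carried several and 9160 were not named. Probe sets with several symbols were not used to name a gene. Rbm3, 1 of the 16 genes set to be reported in any case, has only such probe sets, and their values, from a test of all 22519 probe sets past the filter, are given as those of the probe sets, a choice made after they were seen. Of the other fixed genes 1 was not analysed here. Each array was scaled to the mean of the 8 trimmed means (factors 0.848 to 1.60), values under the 25th percentile of all values (9.80) were raised to that floor, and log2 was taken. Each of 18193 genes was represented by its probe set with the highest mean, and the 11525 genes at or above the median mean of all probe sets (a signal of 36.3) were tested. For 5 genes of the lists an older symbol was matched through its synonym.

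The comparison was 31.5 °C minus 37 °C, fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The temperature was the only term. Whether the replicate numbers pair the arrays was checked from the deviations of each array from its group mean: the arrays of 1 number correlated across genes at 0.541, 0.422, 0.497 and 0.614, against at most 0.0566 for arrays of different numbers. The numbers therefore pair the arrays, and the fit with the number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

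Lists of genes (31, of pathways, cell types and complexes) were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists with at least 5 measured genes. Beside it stand camera with an estimated correlation and fry. Counts of list members are given over all genes tested and adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and the 10 largest falls past the threshold without overlap between temperatures (unnamed transcripts give way to the next named gene), up to 3 genes of smallest p in each list, and 16 fixed genes, of which 14 had a tested probe set of their own. It gave 120 genes, of which some that did not pass are given only within the counts of their lists. Genes outside the rule are named where a count of 5 or fewer or a hypothesis called for them.

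Array quality was compared between temperatures with exact two-sided permutation tests of 10 measures. The ratio of the 3′ to the 5′ actin control was 1.21 ± 0.0415 (SD, n = 4) at 31.5 °C and 1.24 ± 0.0431 at 37 °C (exact p = 0.429, adjusted 0.914). At most 0.708% of values were identical between 2 arrays. The procedure was tested on simulated data in 10 simulations with 200 changed genes each. It recovered 39.4% of changes of 0.5 on the log2 scale, 91.5% of changes of 1 and 99.2% of changes of 2. Of the calls, 5.57% were false. A list shifted by 0.3 was called in 10 of 10 simulations. The simulated genes varied independently of each other and the simulated arrays held no pairs, unlike the data. These rates therefore need not hold for the data, least of all for the list test.

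The alternatives tried were quantile and median scaling, no floor with a pseudocount of 1, a floor at the 50th percentile, no filter, a filter at the 70th percentile, the mean of a gene's probe sets, all probe sets tested singly, probe sets with _x_at or _s_at endings left out, an intensity trend, array weights, the replicate block, an unadjusted p, and leaving out each array or each pair. For a single comparison of means with 4 against 4 arrays the smallest exact permutation p is 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.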

Results

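Oligodendrocyte precursor cells, the dividing cells of the brain that give rise to myelin-forming oligodendrocytes, were grown from the cerebral hemispheres of ICR mouse embryos aged 15 days. After 5 days in medium with 10% serum the cells were moved to serum-free medium and kept for 48 hr at 37 °C or at 31.5 °C. Total RNA was read on whole-genome expression arrays, 4 at each temperature. Each array gives a fluorescence signal for 45101 probe sets, and the number of arrays limits the precision. The trimmed mean of the deposited signal was 238, 203, 224 and 189 in replicates 1 to 4 at 31.5 °C. At 37 °C it was 248, 241, 208 and 132. The labels speak of 3 mice per group and do not say whether the 4 replicates were separate cultures, so each error and p measures only the spread between these samples. Signals are given as mean ± SD (n = 4 arrays per temperature), log2 changes as the 31.5 °C level minus the 37 °C level ± SE. Where an alternative processing ended the call of a gene, "up to" gives its highest adjusted p over the alternatives. For a value that did not pass and that moved by more than 1.5 times, "with 1 array left out" gives its range over the 8 fits without an array. Such a fit leaves the other array of the pair unmatched, so the range also holds differences between pairs.

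The comparison asks which transcripts differ between precursor cultures kept at a hypothermic and at a normal temperature. The cold-inducible RNA-binding gene Cirbp was 3.86-fold higher at 31.5 °C, 11 of 21 measured NRF2 antioxidant genes rose, and 18 of 28 measured markers of differentiating and myelinating oligodendrocytes fell. Of the 11525 genes tested, 1775 changed, 880 of them higher and 895 lower at 31.5 °C. Among the 150 that changed at least 2-fold, 51 were higher and 99 lower. The median size of a change past the threshold was 0.51 on the log2 scale. The 4 values at 1 temperature all lay above the 4 at the other for 2559 genes, 22.2% of those tested, where chance gives 2.86%. With the arrays scaled to a common median, which moved the median of all genes by 0.09 on the log2 scale, 725 genes changed, 62.6% of them higher against 49.6% before. Of the genes changed at least 2-fold, 53% were then higher, against 34% before. With the replicate number as a block, 3548 genes changed, 1772 of them among the 1775.

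Among the 10 largest rises, Gsta2 (probe set 1421040_a_at), a glutathione transferase, rose from 76.8 ± 27.8 to 399 ± 124, a 5.26-fold difference (adjusted p = 0.00192). Aldh3a1 (1418752_at), an aldehyde dehydrogenase, rose from 22.9 ± 2.51 to 91.5 ± 19.0, and Gsta3 (1423436_at), a further glutathione transferase, from 35.7 ± 6.72 to 115 ± 24.0. Cirbp (1416332_at) rose from 424 ± 105 to 1609 ± 201 (adjusted p = 0.000876), and was 1 of 4 measured cold-inducible RNA-binding genes, of which the other 3 did not pass; adjusted over the list alone, 1 rose as well. The median of those 4 genes was -0.08 and their mean 0.40, so the sign differs, and the list was too short for a list test. Rbm3, a further cold-inducible RNA-binding gene, has no probe set of its own: the 2 annotated to it also carry a pseudogene, so their values are assigned to neither and enter no count of genes. Of these 1422660_at rose from 2376 ± 175 to 6716 ± 336 (1.501 ± 0.09, adjusted p = 0.000155 over all probe sets). The dimmer 1429169_at fell from 102 ± 5.30 to 31.5 ± 7.61 (-1.74 ± 0.18, adjusted p = 0.00113). Arrdc4, an arrestin-like gene regulated by glucose supply, rose by 1.89 on the log2 scale, or 1.1 with the mean of its probe sets. Nqo1, a quinone reductase, rose by 1.72, Mir22hg, the host gene of a microRNA, by 1.59, the carboxypeptidase gene Agbl3 by 1.54, the AP-1 gene Fosl1 by 1.53 and the long noncoding transcript Mdrl by 1.48.

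The 10 largest falls included Mobp and Cldn11 of the myelinating oligodendrocyte list. Mobp (1433785_at), a structural myelin gene, dropped from 304 ± 211 to 10.0 ± 7.19, near the floor of 9.80, to which 2 of the 4 arrays at 31.5 °C were set. The size of its log2 change therefore depends on the floor: -4.39 as processed (adjusted p = 0.000876), -2.77 with the floor at the median of all values and -4.86 with no floor. On the log2 scale the noncoding transcript Dleu2 changed by -2.96, Ddc, the decarboxylase of dopamine and serotonin synthesis, by -2.88, and Tppp, a tubulin-binding gene of oligodendrocytes, by -2.47. The histone gene H2bc18 changed by -2.22, the crystallin gene Crygs by -1.93 and the transglutaminase gene Tgm2 by -1.91. Cldn11, a tight-junction gene of myelin, changed by -1.71, and S100b, a calcium-binding gene of glia, by -1.67. Aldh1a1, an enzyme of retinoic acid synthesis, fell by 1.71 (adjusted p = 0.0252, up to 0.0735). The higher floor also shrank the changes of the dim genes to 1.22 for Aldh3a1, 0.72 for Agbl3, -1.84 for Dleu2, -1.02 for Crygs, -1.24 for Tgm2 and -0.93 for Aldh1a1. It ended the call of Aldh1a1, as did leaving out the filter, or replicate 2 or 3 at 31.5 °C.

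**Figure D1:**
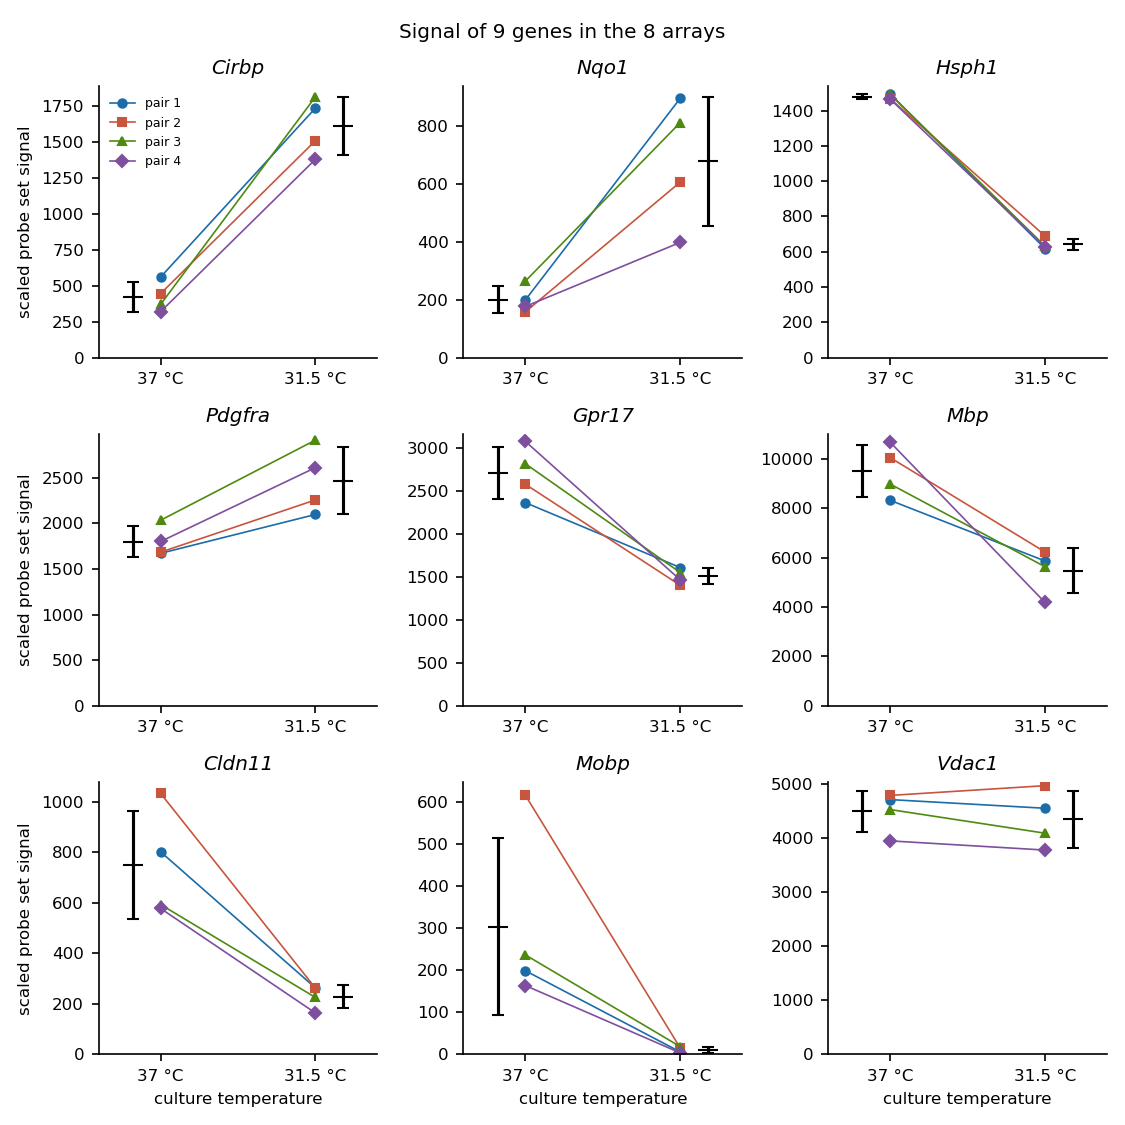
Scaled probe set signal (linear axis from 0) of 9 genes at 37 °C and 31.5 °C. Coloured points joined by lines are the 2 arrays of 1 replicate number, black bars the mean ± SD of 4 arrays; Cirbp lies near 424 at 37 °C and 1609 at 31.5 °C, and Mbp near 9500 and 5474.

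Markers of differentiating and myelinating oligodendrocytes were lower at 31.5 °C. Of the 28 measured, 18 fell, 0 rose and 10 did not pass the test; adjusted over the list alone, 20 fell, and with the block 20 fell and 1 rose. Mbp (1433532_a_at), the myelin basic protein gene, fell from 9500 ± 1054 to 5474 ± 895, a log2 change of -0.80 ± 0.14 (adjusted p = 0.00841), lower in each of the 4 pairs. Mag (1460219_at), the gene of a myelin adhesion protein, fell from 649 ± 258 to 197 ± 25.4 (-1.65 ± 0.24, adjusted p = 0.00445). Cldn11 (1416003_at) fell from 752 ± 214 to 228 ± 46.7 (-1.71 ± 0.22, adjusted p = 0.00311). The median change of the list was -0.65, between -0.38 and -0.85 in the 4 pairs (camera, adjusted p = 5.92e-09; adjusted p = 0.405 with an estimated correlation).

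Precursor markers moved both ways. Among 20 measured, 2 rose, 5 fell and 13 did not pass; adjusted over the list alone, 3 rose and 5 fell, and with the block 4 and 6. Pdgfra (1421917_at), the growth factor receptor that marks precursors, rose from 1798 ± 168 to 2469 ± 365 (0.45 ± 0.12, adjusted p = 0.0373, up to 0.0926), and Lhfpl3 by 0.67 (adjusted p = 0.0373, up to 0.091). Gpr17, a receptor of cells at the step between precursor and oligodendrocyte, fell by 0.84 (adjusted p = 0.00242), and the matrix gene Matn4 changed by -0.87 (adjusted p = 0.00682). Tnr, a further matrix gene, fell by 0.73 (adjusted p = 0.0265, up to 0.0701), Vcan changed by -0.46 (up to 0.185; -0.24 with the mean of its probe sets) and the transcription factor gene Nkx2-2 by -0.51 (up to 0.203). Factors expressed through the whole lineage did not pass: Olig1 was at 6727 ± 390 and 6752 ± 646 (adjusted p = 0.991), Olig2 changed by -0.21 ± 0.12 (adjusted p = 0.278) and Sox10 by -0.36 ± 0.14 (adjusted p = 0.111, from 0.0368 to 0.297 over the alternatives). Sox10 passed without replicate 1 at 37 °C (-0.47, adjusted p = 0.043) or without pair 1 with the block (-0.49, adjusted p = 0.0368). The small value of Olig1 is above 0 with quantile or median scaling or array weights (-0.054 to 0.055 with 1 array left out). Cspg4, the NG2 proteoglycan gene, was 0.20 ± 0.19 higher (adjusted p = 0.514; 0.042 to 0.30 with 1 array left out). The list test gave adjusted p = 0.342 at a median of -0.11 (-0.21 to -0.094 with 1 array left out).

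Genes of the NRF2 antioxidant response, the program that makes glutathione and its enzymes, rose. In this list 11 of 21 measured genes rose, 0 fell and 10 did not pass; adjusted over the list alone, 13 rose, and with the block 16. All 21 had a positive value. Nqo1 (1423627_at) rose from 200 ± 46.4 to 679 ± 223 (1.72 ± 0.26, adjusted p = 0.00524), and Srxn1 (1426875_s_at), which restores oxidised peroxiredoxins, from 888 ± 163 to 2260 ± 415 (1.35 ± 0.18, adjusted p = 0.00332). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose by 1.02 (adjusted p = 0.00238), and the transferase gene Gsta4 by 1.17 (adjusted p = 0.0038). The median change was 0.58, and 0.54, 0.63, 0.51 and 0.49 in pairs 1 to 4 (camera, adjusted p = 5.92e-09; adjusted p = 0.498 with an estimated correlation).

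Subunits of the proteasome, which degrades tagged proteins, were slightly higher together. Of 32 measured, 11 rose, 0 fell and 21 did not pass; adjusted over the list alone, 22 rose, and with the replicate block 20. Psmc1 rose by 0.40 (adjusted p = 0.0168, up to 0.102), Psmd1 by 0.33 (adjusted p = 0.0176, up to 0.097) and Psmd13 by 0.40 (adjusted p = 0.0211, up to 0.547). With the mean of each gene's probe sets the changes were 0.20 for Psmc1 and 0.10 for Psmd13. The list's median was 0.27, with 31 of its genes above 0 (camera, adjusted p = 5.92e-09; adjusted p = 0.498 with an estimated correlation).

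Circadian clock genes were higher at 31.5 °C. In this group 8 of 16 rose, 0 fell and 8 did not pass; adjusted over the list alone, 9 rose and 1 fell, and with the block 10 and 1. Tef (1424175_at), a clock-driven transcription factor gene, rose from 480 ± 51.5 to 801 ± 35.3 (0.74 ± 0.09, adjusted p = 0.00284). Ciart, a repressor of the clock, rose by 0.99 (adjusted p = 0.0163, up to 0.0571) and Per2, a core clock gene, by 0.48 (adjusted p = 0.0166, up to 0.0537). The median was 0.40 (camera, adjusted p = 0.000278; adjusted p = 0.317 with an estimated correlation). Each temperature was sampled at 1 time, so phase and level are not separated.

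Chaperones of the endoplasmic reticulum and genes of the unfolded protein response were lower. Of the 24 measured, 1 rose, 9 fell and 14 did not pass, and the same counts were found adjusted over the list alone; with the block 1 rose and 12 fell. Hsp90b1 (1415889_a_at), an abundant chaperone of this compartment, fell from 2488 ± 175 to 1736 ± 131 (-0.52 ± 0.09, adjusted p = 0.00821, up to 0.0793). Sdf2l1 fell by 0.96 (adjusted p = 0.0134) and Xbp1, a transcription factor gene of the response, changed by -0.44 (adjusted p = 0.0162, up to 0.175). Trib3, a stress-induced pseudokinase gene, rose by 0.47 (adjusted p = 0.0405, up to 0.532). The median was -0.23, or -0.14 with median scaling (camera, adjusted p = 0.000287; adjusted p = 0.317 with an estimated correlation). Among 29 cytosolic and mitochondrial heat shock chaperones, 6 fell, 1 rose and 22 did not pass; adjusted over the list alone, 7 fell and 2 rose, and with the replicate block 8 and 3. Hsph1 (1425993_a_at), a co-chaperone of the heat shock response, fell from 1479 ± 15.3 to 641 ± 32.4 (-1.21 ± 0.07, adjusted p = 0.000133). Serpinh1, which this list holds although it encodes a collagen chaperone of the endoplasmic reticulum, fell by 1.0 (adjusted p = 0.0051). Chordc1, an Hsp90 partner, changed by -0.68 (adjusted p = 0.00965, up to 0.0606). Hspa4 rose by 0.38 (adjusted p = 0.0185, up to 0.142), while with the mean of its probe sets its value was -0.64. The list test gave adjusted p = 0.247 at a median of -0.10 (-0.12 to -0.057 with 1 array left out).

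**Figure D2:**
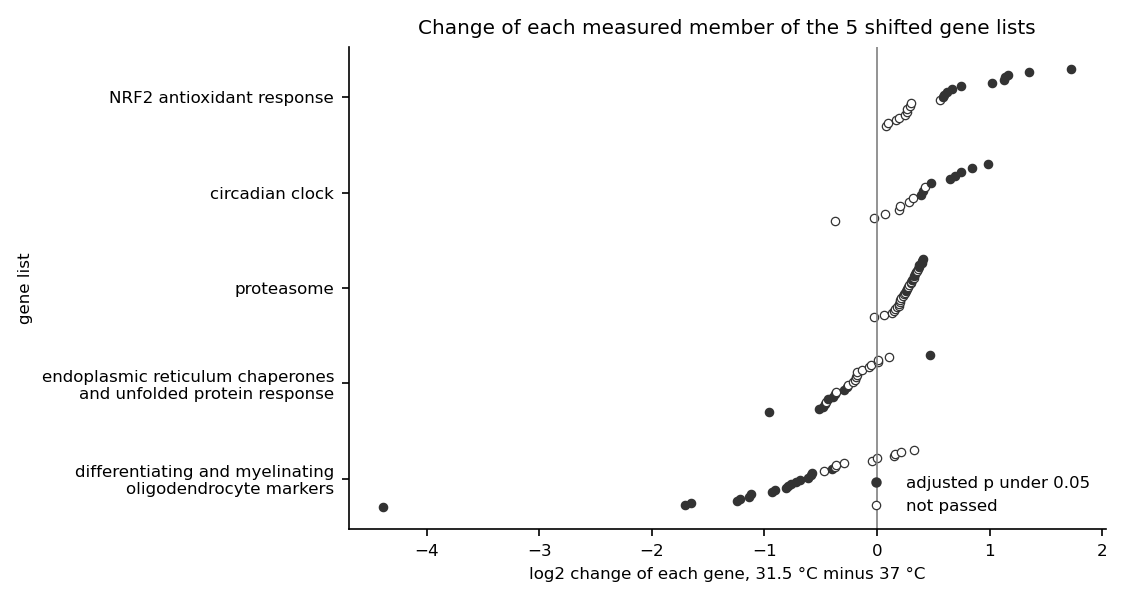
Log2 change (31.5 °C minus 37 °C) of each measured gene of the 5 lists past the threshold of camera with its preset correlation, 1 point per gene, filled where the gene passed the test. All 21 NRF2 genes and 31 of 32 proteasome genes lie above 0, and 24 of 28 oligodendrocyte markers below 0.

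Markers of other cell types that a mixed culture can hold were examined beside these groups. Of 24 microglia and macrophage markers, 1 fell and 23 did not pass; adjusted over the list alone 0 did, with 4 lower and 0 higher at an unadjusted p under 0.05 in limma. Fcrls fell by 1.58 (adjusted p = 0.0426, up to 0.118). C1qb, a complement gene, had -1.17 ± 0.37 (adjusted p = 0.0659, from 0.00117 with the block to 0.164 over the alternatives), the lysozyme gene Lyz2 -0.57 ± 0.20 (adjusted p = 0.0953, from 0.0106 with the block to 0.197 over the alternatives) and Aif1 -0.26 ± 0.34 (adjusted p = 0.649; -0.46 to -0.017 with 1 array left out), all lower in each of the 4 pairs. The list's median was -0.31 (camera, adjusted p = 0.114; -0.47 to -0.18 with 1 array left out). With the block 11 fell and the list passed (adjusted p = 0.00046; adjusted p = 0.821 with an estimated correlation); over the 23 alternatives it passed in 10, with adjusted p from 2.3e-05 to 0.436. Astrocyte markers gave 1 fall, S100b (-1.67 ± 0.12, adjusted p = 0.000336), which oligodendrocytes also express, 0 rises and 24 that did not pass, and the same counts adjusted over the list alone; 2 were higher and 5 lower at an unadjusted p under 0.05. With the block 4 rose and 11 fell. Gfap, the intermediate filament gene of astrocytes, was at 2245 ± 968 against 3519 ± 1480 (-0.64 ± 0.36, adjusted p = 0.264, from 0.00326 with the block to 0.481 over the alternatives), with -0.41 when replicate 1 at 37 °C was left out. Within pairs 1 to 4 the change of Gfap was -0.59, -0.74, -0.76 and -0.48. The astrocyte list had a median of -0.19 (adjusted p = 0.442), a value that single arrays move: it was -0.060 without replicate 1 and -0.097 without replicate 3 at 37 °C, -0.097 without replicate 4 at 31.5 °C and -0.35 without replicate 4 at 37 °C. Within pairs 1 to 4 the median was -0.095, -0.064, -0.24 and -0.27. With the mean of probe sets it was 0.00099.

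Neuron markers split. Among 30, 3 rose, 2 fell and 25 did not pass; adjusted over the list alone 3 rose and 3 fell, and with the block 3 and 11. The interneuron factor genes Dlx1 and Dlx2 rose by 0.61 (adjusted p = 0.00899) and 0.43 (up to 0.0887), and the neurofilament gene Nefm by 0.71 (adjusted p = 0.0193, up to 0.0553). Gap43, a growth cone gene, fell by 0.63 (adjusted p = 0.0299, up to 0.097) and Tbr1, of cortical projection neurons, changed by -0.59 (up to 0.17). Tubb3, a neuronal tubulin gene, had -0.21 ± 0.12 (adjusted p = 0.278, from 0.0457 with the block to 0.705 over the alternatives). The list's median was -0.21 (-0.34 to -0.15 with 1 array left out; adjusted p = 0.213, and 0.0236 with the block; adjusted p = 0.885 with an estimated correlation), and over the 23 alternatives it passed in 5, with adjusted p from 0.000443 to 0.473. Of 18 neural stem and progenitor markers, 4 rose, 0 fell and 14 did not pass, and the same counts were found adjusted over the list alone; with the block 5 rose and 1 fell. The 4 were Sox1 (0.48, adjusted p = 0.019, up to 0.251; 0.24 with the mean of its probe sets), Gli3 (0.39, up to 0.105), Msi1 (0.39, up to 0.333) and Notch1 (0.43, up to 0.102). The list test gave adjusted p = 0.342 at a median of 0.03, whose sign flips without replicate 3 at 31.5 °C (-0.015 to 0.10 with 1 array left out). Of 7 endothelial and pericyte markers 0 passed, also adjusted over the list alone (0 higher and 1 lower at an unadjusted p under 0.05 in limma; 1 and 2 with the block; list median -0.14, adjusted p = 0.693; -0.43 to 0.022 with 1 array left out). Of 22 fibroblast, meningeal and smooth muscle markers, Thy1 fell by 0.55 (adjusted p = 0.0428, up to 0.123), 21 did not pass, 0 passed adjusted over the list alone and 4 fell with the block (list median -0.08, adjusted p = 0.507; -0.25 to -0.011 with 1 array left out, and 0.0056 with median scaling).

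Voltage-dependent anion channels, the pores of the outer mitochondrial membrane, did not pass the test. Vdac1 (1437192_x_at) was at 4342 ± 522 at 31.5 °C and 4489 ± 380 at 37 °C (-0.05 ± 0.11, adjusted p = 0.788), a sign that flips with median scaling or without _x_at and _s_at probe sets (-0.14 to 0.013 with 1 array left out). Vdac2 (1415990_at) was at 4266 ± 193 and 3868 ± 77.0 (0.14 ± 0.07, adjusted p = 0.215), higher in 4 of 4 pairs without overlap, and Vdac3 (1416175_a_at) at 3407 ± 114 and 3307 ± 187 (0.04 ± 0.08, adjusted p = 0.736; 0.010 to 0.074 with 1 array left out). In limma 0 of the 9 channels and partner genes passed, over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05, and 1 rose with the block (list median 0.06, adjusted p = 0.521; 0.036 to 0.077 with 1 array left out).

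**Figure D3:**
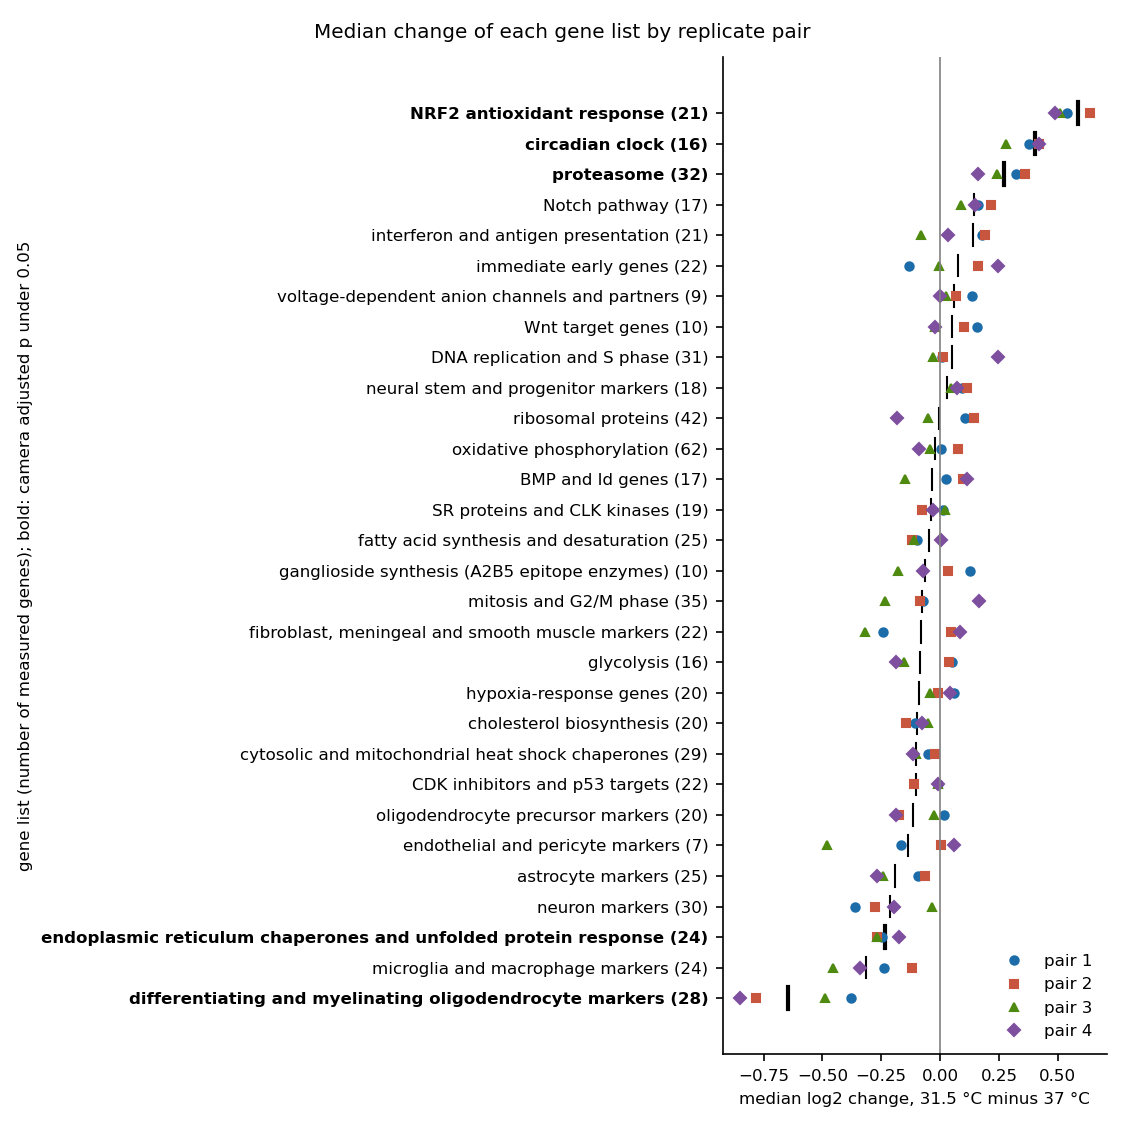
Median log2 change (31.5 °C minus 37 °C) of each of 30 gene lists, with 1 coloured point per replicate pair and a black bar for the median over all arrays. NRF2 genes lie between 0.49 and 0.63 and myelinating oligodendrocyte markers between -0.85 and -0.38 in the 4 pairs.

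By camera with its preset correlation, 5 of 30 lists passed: NRF2 antioxidant response, proteasome, circadian clock, endoplasmic reticulum chaperones and myelinating oligodendrocyte markers. With an estimated correlation 0 passed, 3 at an unadjusted p under 0.05. With the replicate block 7 passed, these 5 and the microglia and neuron lists. By fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, 8 passed: these 5, the heat shock chaperones (adjusted p = 0.00508), the stem and progenitor markers (adjusted p = 0.0385) and the Notch pathway (adjusted p = 0.0171). By fry with the block 8 passed, 7 of them the same: the stem and progenitor markers no longer passed (adjusted p = 0.148), and the microglia and macrophage markers did (adjusted p = 0.0469, against 0.622 without the block).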

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

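Chosen after the results were seen were the tests of astrocytes and microglia for the NRF2 genes, of false calls and of cross-hybridising probe sets for genes with opposite changes, the ranges over left-out arrays and the splits with an estimated correlation; the other tests in this part were set beforehand. Among 328 groups of 4 values examined, 24 held a value far from the other 3, where chance gives about 16.4, or 1 in 20.

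The 35 splits of the 8 arrays into 4 and 4 show how large a result other groupings give. For the 1775 changed genes 1 split of the 35, the real one, gave as many, and the highest other gave 31. For the 150 genes changed at least 2-fold it was again 1 of 35, the highest other giving 9. Since the numbers pair the arrays, the nearer comparison is with the 8 splits that part all 4 pairs, the real one among them. The other such splits gave 0 for both counts, but 8 splits are too few for a share under 0.05. The splits therefore cannot exclude chance for either count of genes. For the 5 lists 32 of the 35 splits gave as many, the highest other giving 14 and those 8 splits at most 8. Chance therefore cannot be excluded for the number of lists. The split with 14 parts 2 of the 4 pairs, and the splits that keep all pairs whole gave 10, 8 and 5. These counts rest on the preset correlation of 0.01, which the estimated one exceeds in 25 of the 30 lists: with an estimated correlation 0 lists passed in each of the 35 splits, the real one included.

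The fall of the myelinating oligodendrocyte markers at 31.5 °C was weighed against a smaller share of the whole lineage and against the array of replicate 4 at 37 °C, whose signal was the lowest. Against the first, the mean change of the list, -0.75, lay below that of Olig1, Olig2 and Sox10, -0.19, by -0.5549 (SE 0.0363; -0.615 to -0.487 with 1 array left out). Against the second, the weakest median with quantile scaling, median scaling or without pair 4 was -0.5587. A lower number of differentiating or myelinating cells or a lower level of these transcripts per cell, either as an effect of temperature, may account for the fall. The arrays hold no measure that parts them.

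The rise of the NRF2 genes was weighed against 1 pair carrying it and against more astrocytes or microglia, which are rich in these enzymes. Against the first, the lowest median in a pair was 0.4861. Against the second, the mean change of the list lay above that of the astrocyte list by 0.8015 (SE 0.0365) and above that of the microglia list by 0.989 (SE 0.0365), with ranges of 0.741 to 0.859 and 0.753 to 1.24 with 1 array left out; 1 of 25 astrocyte and 0 of 24 microglia markers stand in another list. Among abundant markers of these cells, Gfap had -0.64 and Lyz2 -0.57, both lower in each of the 4 pairs. In limma neither passed without the block (adjusted p = 0.264 and 0.0953), and both passed with it (adjusted p = 0.00326 and 0.0106). Of the 25 astrocyte markers 11 had a value above 0, and of the 24 microglia markers 4. A response of the cells to the lower temperature may account for the rise, as a hypothesis found and tested on the same arrays.

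Some genes had probe sets changed in opposite directions. Fam120b rose by 1.22 on 1438427_at and fell by 0.86 on 1435668_at, and Sin3b rose by 0.99 on 1434637_x_at and fell by 0.78 on 1452849_at. Both are named because the smaller of their rise and fall was the largest among such genes. Rps6, Srsf6 and Hspa4 also had probe sets of both directions. Of the 419 genes with at least 2 changed probe sets 64 did so, 15.27% (exact 95% interval 11.97 to 19.08). Cross-hybridising probe sets with _x_at or _s_at endings are argued against as the whole cause, since 58 of the 64, or 90.62% (80.7 to 96.5), kept opposite calls without them. Neither false calls nor signal near the floor can be told apart from other causes. At 5.57% of the 975 changed probe sets of these genes, false calls could reach at most 12.97% of the genes. That bound needs each false call to fall in another gene and against its other calls, and lies within the interval of 11.97 to 19.08. The rate of 5.57% is that of the simulated test of genes without pairs, not of probe sets. With the replicate block, on the same arrays, 64 of the 64 kept opposite calls (94.4 to 100%). The block leaves each log2 change as it was, so no direction could turn. In 30 of the 64, or 46.88% (34.3 to 59.8), the dimmest changed probe set lay in the lowest 25% of those tested. The dimmest of several probe sets lies there more often than a single one. Genes whose changed probe sets agreed were not compared, so this share has no baseline. The intervals of this paragraph treat the genes as independent, which genes on the same arrays need not be. A change in the use of transcript ends or exons at 31.5 °C stays open and was not tested.

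Single values stood apart in 13 gene groups, given as the gap over the range. At 31.5 °C these were Ddc in replicate 4 (0.854, signal 38.2 against 52.5 to 55.4), Chordc1 in replicate 3 (0.834, 761 against 533 to 566), Tbr1 in replicate 1 (0.893, 41.7 against 34.7 to 35.4), Ndrg1 in replicate 1 (0.907, 224 against 120 to 127), Psmd1 in replicate 4 (0.921, 2438 against 2579 to 2591), Gsta4 in replicate 4 (0.901, 4305 against 5870 to 6073) and Ednrb in replicate 1 (0.8602, 4910 against 4060 to 4169). At 37 °C they were Crygs in replicate 3 (0.887, 87.7 against 74.5 to 75.9), Chordc1 in replicate 2 (0.856, 1070 against 917 to 937), Gli3 in replicate 1 (0.92, 130 against 164 to 167), Nr4a3 in replicate 3 (0.902, 292 against 414 to 430), Fam120b in replicate 4 (0.846, 321 against 275 to 281) and Kit in replicate 3 (0.9102, 143 against 161 to 163).

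The mean log2 level of a list stood apart in 6 groups. Neuron markers were low in replicate 3 at 37 °C (0.898, 8.93 against 9.45 to 9.51), and fibroblast, meningeal and smooth muscle markers high in replicate 4 at 31.5 °C (0.876, 8.56 against 7.79 to 7.88). Fatty acid genes were high in replicate 1 at 31.5 °C (0.873, 9.84 against 9.73 to 9.75) and ribosomal protein genes low there (0.908, 11.99 against 12.09 to 12.10). Ganglioside genes were high in replicate 4 at 37 °C (0.839, 7.46 against 7.28 to 7.31) and BMP and Id genes in replicate 1 at 37 °C (0.8293, 8.38 against 8.33 to 8.34).

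The control probe sets of 18S ribosomal RNA were high in both arrays of pair 4. The 5′ control was 424 at 31.5 °C (0.848, others 69.4 to 123) and 376 at 37 °C (0.983, others 117 to 121), the 3′ control 205 (0.9003, others 75.9 to 88.7) and 225 (0.873, others 85.6 to 103). The 3′ to 5′ ratio of the Gapdh control was low in replicate 3 at 37 °C (0.935, 0.726 against 0.751 to 0.752). Among the 2020 tested probe sets with no single gene name, which no gene count uses, 262 changed, 145 of them higher and 117 lower at 31.5 °C.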

How the results depend on the processing

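All alternatives were set beforehand, and where a result below moved or reversed the cause was not tested, apart from the fewer arrays or genes that an alternative leaves. The 5 lists past the threshold kept it and their sign in the 23 alternatives of processing and left-out arrays (highest adjusted p = 0.0142, circadian clock), and lost it with an estimated correlation, where 0 lists passed; fry gave 8 and the fit without pair 4 with the block 8. The 1775 changed genes became 725 with median scaling (679 shared), 2977 probe sets when each was tested, 3548 with the block (1772 shared), 3584 at an unadjusted p, and 871 to 1601 with 1 array left out. Leaving out replicate 1, 2 or 3 at 31.5 °C gave 998, 962 and 871, replicate 2 at 37 °C 1025, and the dim replicate 4 at 37 °C 1203. The 150 genes changed at least 2-fold became 57 with the filter at the 70th percentile, 95 with the mean of probe sets and 374 probe sets, and 124 to 188 with 1 array left out. Of the 125 genes followed through the alternatives 106 changed, and of these 38 passed in every alternative that tested them, 22 of the 38 in all 23. Median scaling ended 49 calls, no filter 31, the mean of probe sets 28 and the block 0. Among the 125 genes the block added the calls of Gfap, Tubb3, C1qb, Lyz2 and Mitf. Genes of the naming rule that were not followed also newly passed with the block, such as Irf7 and Ccnd1 (limma adjusted p = 0.00452 and 0.00451). Leaving out replicates 1 to 4 ended 37, 39, 47 and 21 calls at 31.5 °C, and 27, 35, 26 and 35 at 37 °C. Reversed signs were found in 42 list medians and 22 gene values. With median scaling the medians were 0.0056 for fibroblast, 0.012 for mitosis, 0.043 for fatty acid, 0.0047 for glycolysis, 0.066 for oxidative phosphorylation, 0.023 for ganglioside, 0.055 for BMP, 0.050 for SR protein and 0.084 for ribosomal protein genes, and the values 0.037 for Vdac1, 0.087 for Olig1 and 0.034 for Cyp1b1. With quantile scaling ribosomal protein genes had 0.0021 and Olig1 0.019, and with array weights 0.010 and 0.015. Without _x_at and _s_at probe sets ribosomal protein genes had 0.0048 and Vdac1 0.032. With the filter at the 70th percentile hypoxia genes had 0.082, ganglioside genes 0.064 and Wnt targets -0.022. With the mean of probe sets astrocyte markers had 0.00099, hypoxia genes 0.021, Wnt targets -0.024, Hspa4 -0.64, Srsf6 0.31 (adjusted p = 0.037, 0.00136 to 0.102 over the alternatives) and Rps6 0.21. With the block and without pair 1 SR protein genes had 0.049; without pair 3 ganglioside genes had 0.0071, BMP genes 0.062, ribosomal protein genes 0.0037 and Cyp1b1 0.040; without pair 4 oxidative phosphorylation had 0.012, ribosomal protein genes 0.054, Olig1 0.056 and Pmel 0.014. With 1 array left out the medians ran from -0.015 to 0.10 for stem markers, -0.43 to 0.022 for endothelial markers, -0.038 to 0.021 for oxidative phosphorylation, -0.15 to 0.092 for ganglioside genes, -0.065 to 0.018 for BMP genes, -0.0028 to 0.13 for Wnt targets, -0.019 to 0.15 for immediate early genes, -0.082 to 0.042 for SR protein genes, -0.0044 to 0.22 for interferon genes and -0.048 to 0.066 for ribosomal protein genes. The values ran from -0.14 to 0.013 for Vdac1, -0.054 to 0.055 for Olig1, -0.39 to 0.19 for Cyp1b1 and -0.39 to 0.12 for Pmel. The other 2322 gene values, 683 list medians and all 41 values of the 2 probe sets that Rbm3 shares kept their direction and their side of the threshold, 446 gene values and 5 medians fell short of it and 29 and 19 newly passed. Signals near the floor of 9.80 limit what dim genes can show.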

Other observations

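The genes Trib3, Hspa4, Lhfpl3, Vcan, Nkx2-2, Dlx2 and Tbr1 above, and Dll1, Cers6, Atp5h, Ndufv1, Atf3 and Srsf2 here, fall outside the rule for named genes and were chosen after their values were seen, as were the genes and tests of the retinoid, glucose-sensing, aryl hydrocarbon receptor and pigment hypotheses.

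Lists of growth and signalling genes did not pass the list test of camera, and of them the Notch pathway passed by fry (adjusted p = 0.0171). Of 31 replication genes 2 rose, Chaf1b (0.71, adjusted p = 0.00679, up to 0.0838) and Rfc3 (0.45, up to 0.0611), 1 fell, the polymerase gene Pola1 (-0.64, up to 0.0901), and 28 did not pass; adjusted over the list alone the counts were the same, and with the block 4 and 2 (median 0.05, adjusted p = 0.445). Of 35 mitosis genes Cdca3 rose (0.64, up to 0.0653), Ube2c fell (-0.49, up to 0.192) and 33 did not pass; adjusted over the list alone 0 passed, 2 were higher and 6 lower at an unadjusted p under 0.05 in limma, and with the block 2 rose and 2 fell (median -0.08, adjusted p = 0.35). Over the 23 alternatives the mitosis list passed in 1, without pair 4 with the block (-0.16, adjusted p = 0.00903; the others up to 0.933). Mki67, a marker of dividing cells, had -0.31 ± 0.11 (adjusted p = 0.0982, from 0.0251 to 0.402 over the alternatives), and passed with array weights (-0.37), without replicate 4 at 31.5 °C (-0.40) and without pair 4 with the block (-0.45). Of 22 CDK inhibitors and p53 targets the death gene Pmaip1 rose (0.64, up to 0.0524), Cdkn2d fell (-0.31, up to 0.355) and 20 did not pass; the counts were 1 and 1 adjusted over the list alone, and 2 and 2 with the block (median -0.10, adjusted p = 0.693). In the Notch pathway 3 of 17 rose, Mfng (0.48, up to 0.0506), Notch1 and the ligand gene Dll1 (0.37, up to 0.125), Dner fell (-0.38, up to 0.264) and 13 did not pass; adjusted over the list alone the counts were the same, and with the block 5 and 1 (median 0.14, adjusted p = 0.247). Among 17 BMP and Id genes Bmp4 (-0.45, up to 0.217) and Smad7 (-0.45, up to 0.235) fell and 15 did not pass, the same adjusted over the list alone, with 2 rises and 2 falls with the block (median -0.03, adjusted p = 0.745). Of 10 Wnt targets Tcf7l2, which the myelinating list also holds, fell (-0.40, up to 0.247) and 9 did not pass; 0 passed adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and with the block 2 rose and 1 fell (median 0.05, adjusted p = 0.875). Of 22 immediate early genes Fosl1 and Egr1 (0.69, adjusted p = 0.0088) rose, Nr4a3 (-0.91, adjusted p = 0.00546) and Atf3 (-0.50, up to 0.102) fell and 18 did not pass, with 2 and 2 adjusted over the list alone and 4 and 2 with the block (median 0.08, adjusted p = 0.521). With the mean of probe sets the changes were 0.46 for Chaf1b, -0.32 for Pola1 and -0.76 for Smad7.

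Metabolic, splicing, interferon and ribosomal lists did not pass the list test of camera or of fry. Of 20 cholesterol synthesis genes Msmo1 (-0.35, up to 0.301) and Sc5d (-0.36, up to 0.34) fell and 18 did not pass, the same adjusted over the list alone, with 2 rises and 6 falls with the block (median -0.10, adjusted p = 0.342). Of 25 fatty acid genes Me1, which the NRF2 list also holds, rose (0.67, up to 0.0551), Elovl6 (-0.40, up to 0.203), Elovl7 (-0.62, up to 0.0787) and Cers6 (-0.59, up to 0.122) fell and 21 did not pass, the same adjusted over the list alone; the block gave 2 and 5 (median -0.05, adjusted p = 0.342). Of 20 hypoxia-response genes P4ha1 (-0.57, up to 0.0816), Pdk1 (-0.63, up to 0.951; -0.05 with the mean of its probe sets) and Ndrg1 (-0.74, up to 0.113) fell and 17 did not pass, the same adjusted over the list alone; the block gave 5 rises and 3 falls (median -0.09, adjusted p = 0.786). Of 62 oxidative phosphorylation genes Ndufv1 rose (0.28, up to 0.194), Ndufb2 (-0.44, up to 0.31), Atp5e (-0.32, up to 0.362), Ndufc1 (-0.32, up to 0.27) and Atp5h (-0.26, up to 0.454) fell and 57 did not pass; adjusted over the list alone 1 fell, and with the block 4 rose and 6 fell (median -0.02, adjusted p = 0.687). In limma 0 of 16 glycolysis genes passed, also adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05, and 1 rise and 3 falls with the block (median -0.08, adjusted p = 0.452). Of 10 ganglioside synthesis genes 0 passed, also adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and 1 rose and 1 fell with the block (median -0.07, adjusted p = 0.875). Of 19 SR protein and CLK kinase genes, which act in splicing, Srrm1 (0.56, up to 0.559; 0.13 with the mean of its probe sets) and Srsf2 (0.28, up to 0.386) rose, Srsf6 (-0.50, up to 0.102) and Tra2a (-0.54, up to 0.0588) fell and 15 did not pass, the same adjusted over the list alone, and 3 and 3 with the block (median -0.04, adjusted p = 0.875). The direction of Srsf6 depends on the probe set: 1448454_at fell, 1416721_s_at rose by 0.66 (adjusted p = 0.00378), and the mean of its probe sets rose by 0.31 (adjusted p = 0.037). Of 21 interferon and antigen presentation genes Rsad2 rose (1.0, adjusted p = 0.0132), Gbp2 fell (-0.68, up to 0.155) and 19 did not pass; adjusted over the list alone 1 rose, and the block gave 3 and 1 (median 0.14, adjusted p = 0.445). Of 42 ribosomal protein genes Rps6 fell (-0.62, up to 0.356; 0.21 with the mean of its probe sets) and 41 did not pass; 0 passed adjusted over the list alone, 1 was higher and 2 lower at an unadjusted p under 0.05, and 3 fell with the block (median -0.00, adjusted p = 0.875). With 1 array left out the median of each list of this and the preceding paragraph other than cholesterol synthesis moved by more than 1.5 times or changed sign, between -0.15 and 0.22. With the mean of probe sets the changes were -0.22 for Sc5d and -0.28 for Ndufb2, and with median scaling -0.17 for Atp5h.

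Retinoid genes are a further hypothesis: their falls may reflect lower retinoic acid signalling at 31.5 °C. Of 12 measured, Aldh1a1, Tgm2, Dhrs3 (-1.09, up to 0.0732), Rarb (-0.83, up to 0.11) and Rdh5 (-0.79, up to 0.0827) fell and Rdh10 rose (0.41, up to 0.102). In limma Cyp26b1 (-0.12 ± 0.25, adjusted p = 0.788), Rarg (-0.24 ± 0.25, adjusted p = 0.56) and Rdh11 (-0.09 ± 0.08, adjusted p = 0.506) did not pass. Nor did Rai14 (0.09 ± 0.12, adjusted p = 0.662) and Rxra (0.35 ± 0.15, adjusted p = 0.151). Ranges over left-out arrays were not taken for these genes. With the block 6 fell and 1 rose, the added fall being Rxrg (-1.01, adjusted p = 0.0124 in limma with the block and 0.0636 without). The list test gave camera adjusted p = 0.0871 (adjusted p = 0.443 with an estimated correlation). That list holds the genes whose falls prompted it, Aldh1a1 and Tgm2 of the largest falls among them. Its p therefore cannot decide the question, and the hypothesis stays open.

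Arrdc4 and Txnip (0.63, up to 0.107), both known to follow glucose supply through the factor MondoA, rose, which may point to a shift of such targets. Of 9 measured genes Klf10 also rose (0.60, adjusted p = 0.00677) and Mlx, a partner of MondoA, fell (-0.52, up to 0.0829, and -0.34 with the mean of its probe sets). With the block 4 rose and 1 fell, the added rise being Arrdc3 (0.36, adjusted p = 0.0149 in limma with the block and 0.0759 without). Hk2 (0.06), Tkt (0.19), Arrdc2 (-0.002) and Mlxip (-0.10) did not pass in limma, with or without the block. Ranges over left-out arrays were not taken for them. The list test gave camera adjusted p = 0.0871 (adjusted p = 0.47 with an estimated correlation). That list holds Arrdc4 and Txnip, whose rise prompted it, so its p cannot decide the question, and this stays open too.

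Aldh3a1 and Nqo1 are also targets of the aryl hydrocarbon receptor, and a rise of its targets as a group could account for both. The measured targets other than these, Tiparp and Cyp1b1, argue against a rise of the whole group: Tiparp had 0.1408 ± 0.11 (adjusted p = 0.431; 0.052 to 0.20 with 1 array left out), and Cyp1b1 -0.05 ± 0.36 (adjusted p = 0.938; -0.39 to 0.19), against 1.98 ± 0.16 for Aldh3a1 and 1.72 ± 0.26 for Nqo1. Cyp1a1 and Ahrr, further targets, were not among the measured genes, so this argument rests on Tiparp and Cyp1b1 alone. Genes outside the list drawn up for this hypothesis were not weighed as targets. A rise of Aldh3a1 and Nqo1 alone through the receptor stays open.

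Genes known from pigment cells fell: Dct changed by -1.58 (adjusted p = 0.00563), Gpnmb by -1.48 (adjusted p = 0.00917) and Oca2 by -1.20 (adjusted p = 0.00138). Fewer pigment cells at 31.5 °C may be the source, but of the other 4 measured genes of that list 0 passed in limma, also at an unadjusted p under 0.05: Mitf had -0.48 ± 0.22 (adjusted p = 0.17, from 0.00539 with the block to 0.527 over the alternatives; -0.31 with the mean of its probe sets) and Pmel -0.14 ± 0.35 (adjusted p = 0.828; -0.39 to 0.12 with 1 array left out), while Ednrb had 0.08 ± 0.10 (adjusted p = 0.616; 0.016 to 0.12) and Kit 0.08 ± 0.11 (adjusted p = 0.686; 0.029 to 0.17). The list of 7 measured genes gave camera adjusted p = 0.056 (adjusted p = 0.344 with an estimated correlation). It holds Dct, Gpnmb and Oca2, whose falls prompted it, so its p cannot decide the question. With the block the error of Pmel was 0.14 (adjusted p = 0.49), and its change of -0.14 lay well short of those of Dct, Gpnmb and Oca2. Tyr, Tyrp1 and Mlana, further genes of pigment cells, were not among the 7 measured, so they cannot help to decide. Fewer pigment cells at 31.5 °C stay open all the same, since Gpnmb, Mitf, Ednrb and Kit are not specific to pigment cells and Pmel is a single gene.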
